A study of Rattus norvegicus with 18 samples.

How the data were processed

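Total RNA of rat ovarian follicles was labelled with biotin by in vitro transcription and hybridized to Affymetrix arrays with 31099 probe sets, 1 array per sample, per the labels' protocols. The 18 samples formed 6 groups of 3: control PeF, control PoF, IM PeF, IM UF, RU PeF and RU UF. The labels state 3 animals per treatment group at each time but do not tie each sample to an animal, and the p-values measure the spread between samples. The sample titles call the follicles of 22:00 peri-ovulatory, while the study's description calls them pre-ovulatory. The number of arrays limits the precision of every value.

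The deposited values are intensity, given as linear probe set signals with a floor of 1. MAS5 is named in the submitters' processing notes, and its version, scaling target and role are not given in the sources used here. The deposited signals were not scaled to a common level between arrays, as their medians, given for each array in the results, show. Who set the floor is not given in the sources used here. Between 7.04% and 25.1% of the probe sets of an array stood at the floor.

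The design written before the data were examined took the signals as scaled between arrays and used them without further normalization, with quantile normalization as an alternative. Since the medians showed otherwise, quantile normalization was made the main setting, and the signals as deposited became an alternative. This was decided from the medians before any test was run. A pseudocount of 2.79, the 20th percentile of all values, was added before taking log2. The 57 control probe sets were left out, and probe sets above their own array's median on at least 3 of 18 arrays were tested, which left 18155. The 27 control probe sets without a spiked target set the background level: a gene was taken as at background in a group where its signal on all 3 arrays was at or below the highest of them on that array. Among the probe sets, 20826 had 1 gene symbol, 436 several and 9780 none, and the symbols of 20758 were updated or kept through the gene ID. A representative probe set, the one with the highest mean, was taken for each of 10391 genes in counts of genes and in tests of lists.

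Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 18 samples, 12 residual degrees of freedom (median prior degrees of freedom 5.76), a variance trend, and Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were control PoF against control PeF, each treated group against the control of its time, each drug's later against its earlier group, the drugs against each other at each time, and the difference of each drug's effects between the times. An exact permutation test of 3 against 3 samples cannot give a two-sided p under 0.1, and 10% of such splits do not overlap by chance, so single genes were tested through limma alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

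Lists of genes fixed with that design were tested with camera at a preset correlation of 0.01, adjusted over the lists of a kind within a comparison, and again with an estimated correlation. Camera sets a list against the other genes of the same arrays, so a shift of all genes between arrays largely cancels. A call kept under another scaling is therefore little evidence on such a shift. The estimated correlation was run on the normalized signals alone, so calls with the deposited signals rest on the preset one. The 17 pathway lists covered steroidogenesis, cholesterol synthesis, prostaglandin synthesis and signalling, the progesterone receptor and its reported follicular targets, regulators induced by luteinizing hormone, the cumulus matrix, matrix proteases and inhibitors, collagens and structural matrix, cytokines and chemokines, the interferon response, angiogenic factors, hypoxia and glycolysis, the cell cycle, immediate early genes, glucocorticoid receptor targets, the circadian clock and luteal genes. Of 8 cell type lists 6 were tested (granulosa, theca, smooth muscle and pericytes, endothelium, leukocytes and oocyte). Erythrocytes and the epithelium of the ovarian surface had fewer than 5 measured members and gave no result. Counts of members are given over all genes and adjusted over the list alone.

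The genes named were chosen by a rule fixed at the same time, for the control time course, the treated against control comparisons and the comparisons of the drugs. It took the 8 largest rises and the 8 largest falls among called probe sets with 1 gene symbol, 1 per gene, whose 3 values in 1 group lay beyond all 3 of the other. It added up to 3 members with the smallest adjusted p from each list that was called or had at least 3 members called. It also took 18 fixed genes, of which 17 were measured: Ptgs2, Ptges, Pgr, Adamts1, Edn2, Star, Cyp11a1, Cyp17a1, Cyp19a1, Akr1c18 (now Akr1c3), Lhcgr, Areg, Ereg, Has2, Tnfaip6, Il6 and Vegfa, with Ptx3 not measured. Members of a list named outside this rule, such as Slc2a3 in the control time course, Ccnb1 in the RU time course and Mt1 in the test between the times, were chosen after their values were seen.

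The alternatives fixed with the design were the signals as deposited, median scaling, no pseudocount, a pseudocount at the median of all values, no filter, a filter at the 75th percentile, only the compared groups in the fit, a replicate block, a robust variance model, no variance trend, the estimated correlation, the mean of all probe sets of a gene and leaving out each array in turn. Array quality weights and a fit without the 3 dimmest arrays (control PeF 3, IM UF 2 and IM PeF 2) were added after seeing the data. The procedure was tested on simulated data with 200 changed probe sets among 18155: between 74% and 87% of 4-fold changes and between 33% and 41% of 2-fold changes were recovered per comparison, and between 0.862% and 10.2% of calls were false. All simulated arrays had the same spread for a probe set. These shares therefore do not describe comparisons that hold more scattered arrays, such as IM PeF against control PeF.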

Results

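Gene expression was measured on 18 arrays in ovarian follicles of Crl:CD(SD) rats around the time of ovulation. The follicles were cut out of frozen sections 8 micrometres thick by laser microdissection, and the labels state that 15 follicles were taken in each phase. There were 6 groups of 3 samples. Untreated rats gave peri-ovulatory follicles at 22:00 of proestrus (control PeF) and post-ovulatory follicles at 10:00 of estrus (control PoF). Rats given indomethacin (IM), an inhibitor of the cyclooxygenases that make prostaglandins, at 4 mg/kg by mouth at 16:00 of proestrus gave peri-ovulatory follicles at 22:00 (IM PeF) and unruptured follicles at 10:00 of estrus (IM UF). Rats given RU486 (RU), an antagonist of the progesterone and glucocorticoid receptors, at 100 mg/kg by mouth at 10:00 of proestrus gave the matching groups RU PeF and RU UF. At estrus the treated follicles were unruptured and the control follicles ruptured, so treatment and rupture cannot be separated there.

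The arrays differed in brightness. The median signal was 16.2, 22.3 and 4.4 in control PeF 1 to 3 and 25.7, 24.2 and 27.4 in control PoF. It was 19.6, 11.1 and 19.4 in IM PeF and 23.9, 7.68 and 19.6 in IM UF. It was 16.4, 16.9 and 19.6 in RU PeF and 16.9, 17.1 and 16.96 in RU UF. The share of probe sets above the brightest unspiked control probe set, a background level, ran from 45.7% in control PeF 3 to 75.3% in IM PeF 3. The log2 difference between the 3' and 5' probe sets of Gapdh, which grows as RNA is degraded, was 3.72 ± 0.665 (SD, n = 3) in control PeF, 2.22 ± 0.133 in control PoF, 2.99 ± 0.559 in IM PeF, 2.89 ± 0.866 in IM UF, 2.78 ± 0.147 in RU PeF and 3.07 ± 0.202 in RU UF. For Actb it was, in the same order of groups, 5.21 ± 0.874, 5.05 ± 0.130, 4.79 ± 0.307, 5.16 ± 0.174, 5.005 ± 0.240 and 5.22 ± 0.427. The 2 measures did not go together: control PeF 3 had 4.10 for Gapdh and the lowest value of all arrays, 4.23, for Actb. Within groups, the correlation of replicates across probe sets, which are not independent replicates, ran from 0.869 (control PeF 1 and 3) to 0.976 (control PoF 2 and 3). The first principal component held 49.6% of the variance and placed all 9 samples of 22:00 below 0 and all 9 of 10:00 above it. The second, with 11.979%, set control PeF 3 apart at -114. The third, with 9.16%, held all RU samples above 24 and the other samples below 18.

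**Figure D1:**
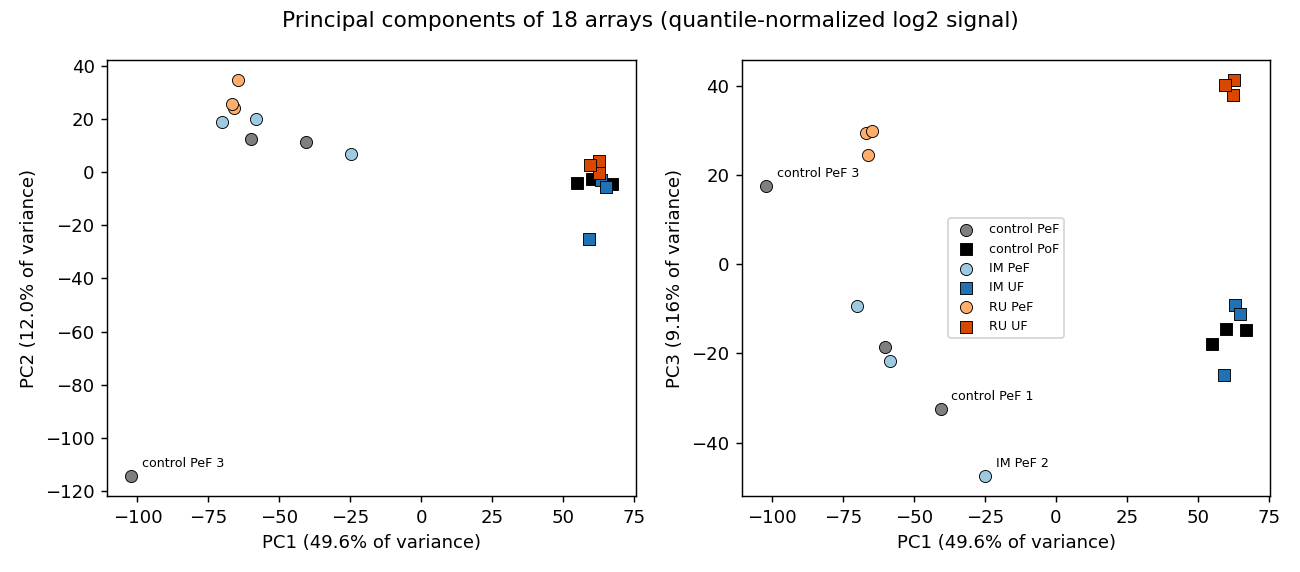
Scores of the 18 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in arbitrary units, coloured by group. Component 1 parts the samples of 22:00 from those of 10:00, component 2 sets control PeF 3 apart at -114, and the RU samples lie at the top of component 3.

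The comparison of control PoF with control PeF asks which genes change as an untreated follicle passes through ovulation. Cyclooxygenase 2 (Ptgs2), which makes the prostaglandins of ovulation, fell 205-fold (log2 difference -7.68 ± 0.83, SE, n = 3 per group, limma adjusted p = 1.83e-06), and the neuropeptide gene Adcyap1 fell 243-fold (-7.93 ± 0.43). The cumulus matrix gene Tnfaip6 fell 19.8-fold (-4.31 ± 0.53), aromatase (Cyp19a1), which makes estradiol, 23.2-fold (-4.54 ± 0.49), and the epidermal growth factor family ligand amphiregulin (Areg) 19.1-fold (-4.26 ± 0.81). The progesterone receptor Pgr stood at 7.18 ± 1.68 log2 units (SD) in control PeF and at background in control PoF (adjusted p = 7.24e-05). Among the genes that rose, Cemip, which degrades hyaluronan, rose 119-fold (6.90 ± 0.32), the vascular peptide apelin (Apln) 31.2-fold (4.96 ± 0.53), the contractile peptide endothelin 2 (Edn2) 18.1-fold (4.17 ± 0.49) and Vegfa 3.79-fold (1.92 ± 0.19). Star, which carries cholesterol into mitochondria, fell 1.87-fold (-0.90 ± 0.14, adjusted p = 8.06e-05) but lay higher (0.42) with the signals as deposited, without normalization between arrays.

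Of 23 measured genes of hypoxia and glycolysis, 18 rose and 1 fell, with the same counts adjusted over the list alone and with median scaling, and 20 and 0 with the deposited signals. The glycolytic enzyme Pfkp rose by 1.73 ± 0.15 and the mitophagy gene Bnip3 by 3.51 ± 0.34, while the glucose transporter Slc2a3 fell (-1.47 ± 0.32). The list's mean was 1.37 (camera adjusted p = 1.04e-05; adjusted p = 0.140 with an estimated correlation). Of 15 regulators induced by luteinizing hormone, 13 fell and 2 did not pass, again the same adjusted over the list alone, among them the inhibin subunit Inha (-1.80 ± 0.19) and the ubiquitin-editing enzyme Tnfaip3 (-1.56 ± 0.22). This list's mean was -1.54 (camera adjusted p = 4.90e-05; adjusted p = 0.140 with an estimated correlation). With median scaling 10 of its members fell (mean -1.32), and with the deposited signals 1 did (mean -0.22, where the median gene stood at 1.38), while camera called it lower in both (7.04e-07 and 3.99e-08). Relative to the mean of the 18 arrays the list stood at 0.08, 0.60 and 1.35 in control PeF 1 to 3, the last being the dimmest array. The other lists were not called. In the structural matrix list 15 of 32 genes rose and 3 fell over all genes and over the list alone (camera adjusted p = 0.289), with Lama1 at 2.32 ± 0.26 and Sparc at 1.21 ± 0.24. Of the smooth muscle and pericyte markers 8 of 13 rose and 1 fell (camera adjusted p = 0.139), and of the theca markers 1 of 10 rose and 5 fell (camera adjusted p = 0.139). The granulosa list had 5 members that rose and 6 that fell of 14 (0.910), the leukocyte list 1 and 1 of 16 (0.910), the endothelial list 1 and 2 of 15 (0.910) and the oocyte list none of 5 (0.544), each with its camera adjusted p. Median, mean and test differed in sign in 3 lists: the glucocorticoid list had a median of 0.12, a mean of -0.25 and a camera direction of down, the clock list -0.22, 0.05 and down, and the leukocyte list 0.11, 0.08 and down.

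In this comparison 7183 of 18155 probe sets were called by limma, 3820 higher and 3363 lower in control PoF, and 4036 of them differed at least 2-fold. Over 1 probe set per gene, 4585 of 10391 genes were called. The split depended on the scaling between arrays: 74.6% of calls were higher with median scaling and 97.5% with the signals as deposited, against 53.2%. With the deposited signals 52 of the 79 called probe sets that the naming rule gave kept their call, 17 lost it and 10 turned direction.

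**Figure D2:**
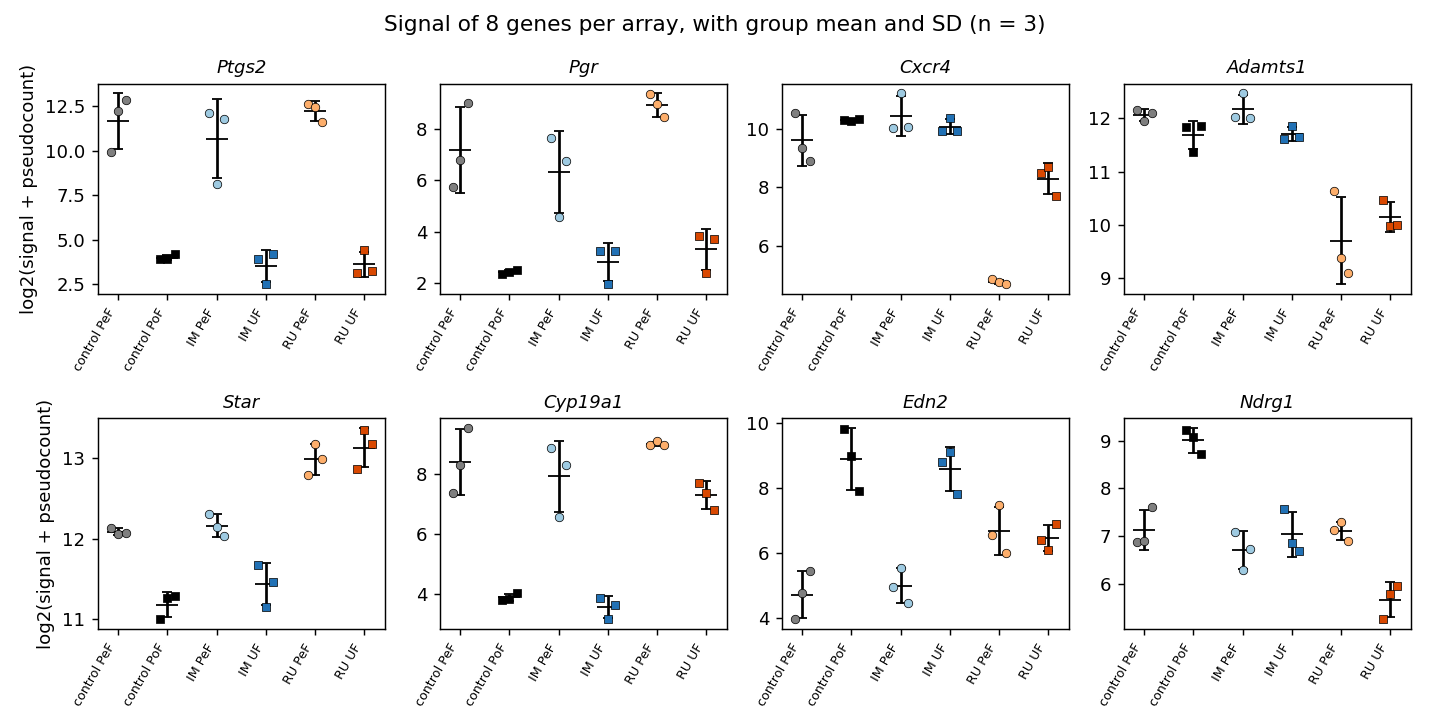
Log2 signal after quantile normalization of Ptgs2, Pgr, Cxcr4, Adamts1, Star, Cyp19a1, Edn2 and Ndrg1 in each of the 18 arrays (points) by group, with the group mean and SD (n = 3). Ptgs2 was low in all groups at 10:00 of estrus, Cxcr4 lay lowest in RU PeF, and Cyp19a1 was higher in RU UF than in the other groups of 10:00.

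The comparison of IM PeF with control PeF asks what blocking prostaglandin synthesis does before rupture. No single gene passed. Ptgs2, the target of the drug, differed by -0.999 ± 0.83 (adjusted p = 0.629), Pgr by -0.86 ± 0.74 (0.643), the matrix protease Adamts1 by 0.10 ± 0.27 (0.903), Star by 0.08 ± 0.14 (0.845) and Tnfaip6 by 0.14 ± 0.53 (0.934). Limma called 0 of 18155 probe sets, and 2074 had an unadjusted p under 0.05. No member of any list was called. The structural matrix list had a mean of -0.16 (camera adjusted p = 0.00246; adjusted p = 0.921 with an estimated correlation), which was 0.05 with median scaling, where the call ended (0.0536), and 0.48 with the deposited signals, where it ended too (0.186). The smooth muscle and pericyte markers had a mean of -0.22 (camera adjusted p = 0.00516; 0.0323 with an estimated correlation), with 2 members lower adjusted over the list alone. Its mean with the deposited signals was 0.27, below the median gene at 0.64, and camera called the list lower there too (0.00433). The endothelial markers had a mean of -0.19 (camera adjusted p = 0.00590; adjusted p = 0.112 with an estimated correlation), or 0.32 with the deposited signals, again called lower than the other genes (0.00757). Without the 3 dimmest arrays none of these lists was called (0.0832 for the matrix list, 0.0972 for each of the cell type lists). Leaving out control PeF 2 gave 27 called probe sets, and weighting the arrays by quality gave 2348. With those weights control PeF 2 (3.97) and IM PeF 3 (7.17) carried most of their groups.

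The comparison of RU PeF with control PeF asks what blocking the progesterone and glucocorticoid receptors does before rupture. The chemokine receptor Cxcr4 fell 28.8-fold (-4.85 ± 0.35, SE, n = 3 per group, adjusted p = 1.17e-06) and Adamts1, a protease required for normal ovulation, fell 5.12-fold (-2.35 ± 0.27, adjusted p = 4.92e-05). Tissue factor (F3), which starts coagulation, fell 13.5-fold (-3.76 ± 0.31), and Xlr5c fell 49.1-fold (-5.62 ± 0.53). Of 14 glucocorticoid receptor targets 11 fell, and 13 when adjusted over the list alone, including the metallothioneins Mt1 (-2.58 ± 0.29) and Mt2A (-2.48 ± 0.31) and the transcription factor Klf9 (-1.15 ± 0.18). The list's mean was -1.31 (camera adjusted p = 5.81e-11; 0.00246 with an estimated correlation). With median scaling 3 members fell (mean -0.97), and with the deposited signals none did (mean -0.41, where the median gene stood at 0.83), while camera called the list lower in both (1.22e-13 and 2.53e-12). Of 19 genes of cholesterol synthesis 14 rose, and 17 when adjusted over the list alone, including Fdps (0.94 ± 0.14), Dhcr7 (1.67 ± 0.27) and Insig1 (1.29 ± 0.29). That list's mean was 0.80 (camera adjusted p = 7.02e-10; adjusted p = 0.0918 with an estimated correlation). With median scaling 12 members rose, and with the deposited signals none did (mean 1.69), with the list called higher in both (6.02e-09 and 1.79e-10).

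Of 13 genes in the list of the progesterone receptor and its reported targets, 6 fell and 1 rose, with 6 and 2 adjusted over the list alone. Besides Cxcr4 and Adamts1, the hypoxia-inducible factor subunit Epas1 fell by 2.06 ± 0.32, although its other probe set differed by 0.99. Edn2 rose (1.96 ± 0.49, adjusted p = 0.0198). The mean was -0.60 (camera adjusted p = 0.00869; 0.0387 with an estimated correlation). With median scaling 3 members fell and 1 rose (mean -0.33), and with the deposited signals 1 fell and 1 rose (mean 0.24, below the median gene at 0.83), and camera called the list lower in both (0.00283 and 0.00600). The call ended without the 3 dimmest arrays (0.0885). Ptgs2 (0.55 ± 0.83, adjusted p = 0.725) and Pgr itself (1.75 ± 0.74, 0.158) did not pass. Star rose 1.86-fold (0.90 ± 0.14), the progesterone-catabolizing enzyme Akr1c3, listed under its earlier name Akr1c18, 3.41-fold (1.77 ± 0.34) and the inhibin subunit Inhbb 3.59-fold (1.84 ± 0.16). Tnfaip3 fell 5.47-fold (-2.45 ± 0.22).

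Of 32 structural matrix genes 12 fell and 1 rose, with 16 and 1 adjusted over the list alone. Col3a1 fell by 1.13 ± 0.15 and lumican (Lum) by 1.37 ± 0.19. The list's mean was -0.52 (camera adjusted p = 3.38e-09; 0.0387 with an estimated correlation). With median scaling 3 members fell and 1 rose (mean -0.22), and with the deposited signals none passed (mean 0.32, below the median gene at 0.83), and camera called the list lower in both (6.41e-07 and 4.95e-04). Markers of other cell types moved with it. Of 13 smooth muscle and pericyte markers 6 fell, and 8 over the list alone, such as Tagln (-1.80 ± 0.24) and Myh11 (-2.11 ± 0.32), with a mean of -0.67 (camera adjusted p = 3.82e-05; 0.00373 with an estimated correlation). With median scaling 4 of them fell (mean -0.49), and with the deposited signals none did (mean -0.0216), with camera calls in both (9.17e-08 and 1.05e-05). Of 15 endothelial markers 2 fell, and 3 over the list alone, with a mean of -0.46, or 0.21 with the deposited signals (camera adjusted p = 0.00141; adjusted p = 0.0638 with an estimated correlation). No endothelial marker passed with median scaling or the deposited signals, and the list was called lower in both (2.99e-04 and 7.37e-04). The theca (0.0659), leukocyte (0.0841), granulosa (0.153) and oocyte (0.0628) lists were not called by camera.

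Limma called 1348 probe sets in this comparison, 617 higher and 731 lower in RU PeF, and 660 differed at least 2-fold. Over 1 probe set per gene, 886 genes were called. The count was 623 without RU PeF 3, 710 without RU PeF 2, 277 with only these groups in the fit (93 higher and 184 lower), 893 with median scaling (673 higher and 220 lower) and 22 with the deposited signals (14 higher and 8 lower). It was 2248 without the 3 dimmest arrays and 3486 with array quality weights. With the deposited signals 10 of the 57 called probe sets that the naming rule gave kept their call, 42 lost it and 5 turned direction.

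**Figure D3:**
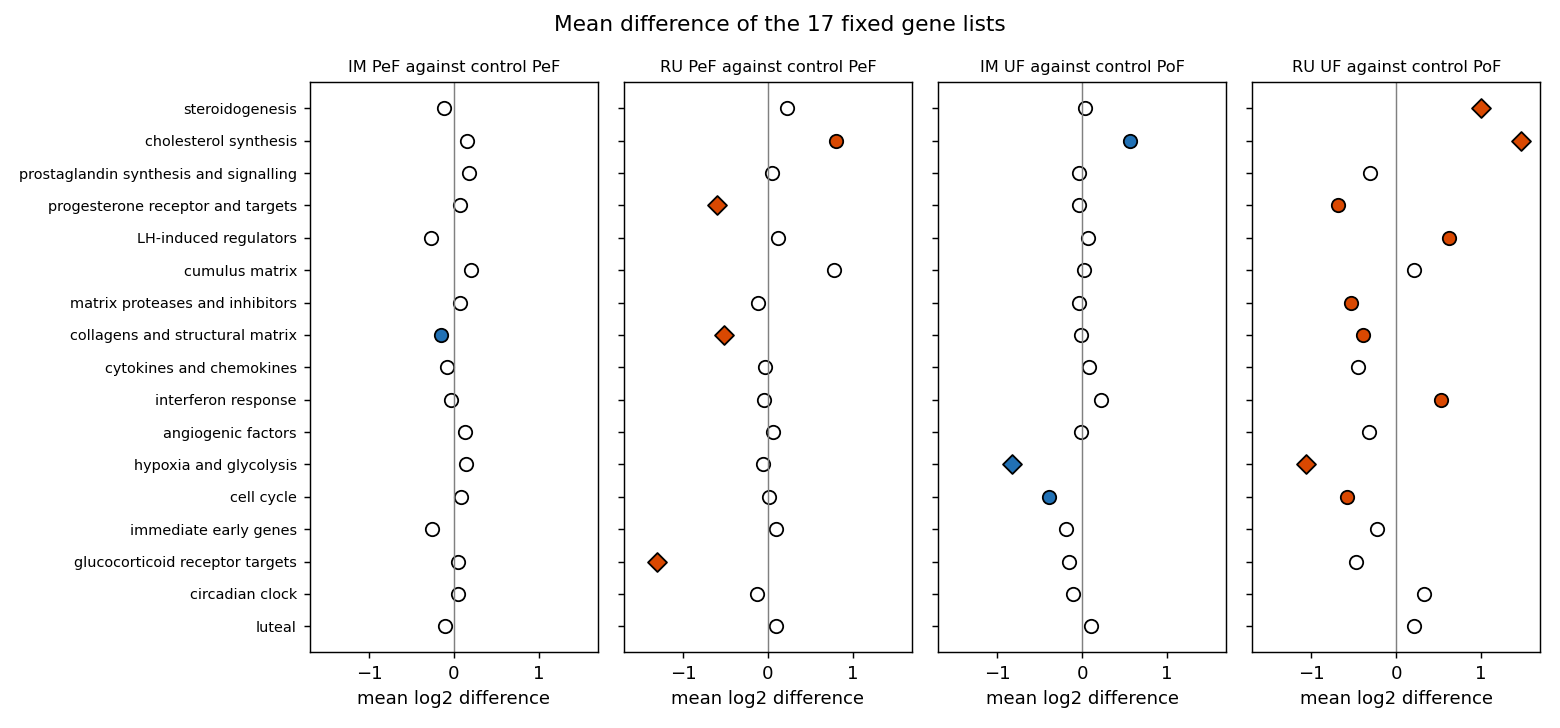
Mean log2 difference of the members of 17 gene lists in the 4 comparisons of treated with control follicles (IM PeF, RU PeF, IM UF and RU UF). Filled points mark lists called by camera and diamonds those also called with an estimated correlation, and the cholesterol synthesis list in RU UF lies farthest to the right with a mean of 1.48 (0.77 with the deposited signals).

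The comparison of IM UF with control PoF asks how follicles that stayed unruptured under indomethacin differ from ruptured ones. The 6 called probe sets were all lower in IM UF. They belonged to Gbe1, which branches glycogen (2.11-fold, -1.08 ± 0.13, SE, n = 3 per group, adjusted p = 0.00169), the hypoxia-responsive Ndrg1 (3.90-fold, -1.96 ± 0.27, 0.0101), heme oxygenase 1 (Hmox1, -1.45 ± 0.22, 0.0247), the endoplasmic reticulum oxidase Ero1a (-1.001 ± 0.16, 0.0379), the X-inactivation transcript Xist (-1.16 ± 0.19, 0.0431) and the oxygen-sensing prolyl hydroxylase Egln3 (-2.99 ± 0.51, 0.0480). Ptgs2 (-0.47 ± 0.83), Edn2 (-0.32 ± 0.49), Star (0.25 ± 0.14) and Vegfa (-0.67 ± 0.19, adjusted p = 0.340) did not pass.

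Of 23 hypoxia and glycolysis genes 2 fell, and 11 when adjusted over the list alone, or 3 with median scaling and 2 with the deposited signals. The list's mean was -0.82 (camera adjusted p = 1.98e-16; 0.00677 with an estimated correlation), and Adm, which encodes a vasodilator peptide, differed by -2.83 ± 0.53 (adjusted p = 0.0772). Of 19 cholesterol synthesis genes none passed over all genes and 10 were higher adjusted over the list alone, with Fdps at 0.80 ± 0.14 (adjusted p = 0.0553) and Mvd at 1.10 ± 0.22 (0.0915). The mean was 0.56, or -0.20 with the deposited signals (camera adjusted p = 3.44e-15; adjusted p = 0.0531 with an estimated correlation). Of 28 cell cycle genes none passed and 3 were lower adjusted over the list alone, with a mean of -0.39 (camera adjusted p = 4.92e-09; adjusted p = 0.382 with an estimated correlation). Endothelial markers had a mean of -0.32 (camera adjusted p = 0.00223; adjusted p = 0.0751 with an estimated correlation). Smooth muscle markers had a mean of 0.22, or -0.57 with the deposited signals (camera adjusted p = 0.0301; adjusted p = 0.0751 with an estimated correlation). Leukocyte markers had a mean of 0.43, or -0.26 with the deposited signals, and 1 member higher over the list alone (camera adjusted p = 0.0301; adjusted p = 0.266 with an estimated correlation). The median gene stood at -0.76 with the deposited signals, and camera called the cholesterol (3.33e-10) and leukocyte (3.16e-07) lists higher than the other genes there too, while the smooth muscle call ended (0.0900). The smooth muscle and leukocyte calls ended without the 3 dimmest arrays (0.0919 and 0.339).

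Limma called 6 probe sets, and 1265 had an unadjusted p under 0.05. The count was 17 without IM UF 1, 2 without control PoF 2 and 1 without control PoF 1, IM UF 2 or IM UF 3. It was 171 with arrays weighted by quality, 13 without the 3 dimmest arrays and 14 with a pseudocount at the median of all values. Of the 6 genes, Gbe1 alone was called whichever array was left out, and it was not called with median scaling or with the deposited signals.

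The comparison of RU UF with control PoF asks the same for RU486. Genes of steroid synthesis stood out. Star rose 3.86-fold (1.95 ± 0.14, SE, n = 3 per group, adjusted p = 5.89e-07), aromatase (Cyp19a1) 10.7-fold (3.42 ± 0.49, adjusted p = 2.44e-04) and Hsd17b7, an enzyme of both estradiol and cholesterol synthesis, 6.88-fold (2.78 ± 0.27, adjusted p = 8.50e-06), while the side-chain cleavage enzyme Cyp11a1 differed by 0.05 ± 0.09 (0.822). Of 13 steroidogenesis genes 6 rose, over all genes and over the list alone, with a mean of 1.00 (camera adjusted p = 1.28e-05; 0.0222 with an estimated correlation). Of 19 cholesterol synthesis genes 17 rose, and all 19 over the list alone, including Tm7sf2 (2.55 ± 0.20), Fdps (1.62 ± 0.14) and Lss (2.22 ± 0.24), with a mean of 1.48 (camera adjusted p = 6.68e-25; 0.0174 with an estimated correlation).

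Of 23 hypoxia and glycolysis genes 10 fell in RU UF, and 12 over the list alone, including Ndrg1 (-3.33 ± 0.27) and Pfkp (-1.36 ± 0.15). The mean was -1.06 (camera adjusted p = 2.76e-09; 0.0222 with an estimated correlation). Of 28 cell cycle genes 4 fell, and 8 over the list alone, including Cdk1 (-1.02 ± 0.22), with a mean of -0.58 (camera adjusted p = 1.13e-06; adjusted p = 0.214 with an estimated correlation). Of 23 matrix proteases and inhibitors 6 fell, and 7 over the list alone, including the plasminogen activator Plat (-2.91 ± 0.45) and Timp1 (-0.97 ± 0.18), with a mean of -0.53 (camera adjusted p = 0.0106; adjusted p = 0.0722 with an estimated correlation). Of 32 structural matrix genes 8 fell and 1 rose, with 14 and 1 over the list alone, including Lox (-1.38 ± 0.22), with a mean of -0.39 (camera adjusted p = 5.01e-05; adjusted p = 0.109 with an estimated correlation). Of 13 genes in the progesterone receptor list 4 fell, and 5 over the list alone: Epas1 (-2.20 ± 0.32), Cxcr4 (-2.01 ± 0.35), Adamts1 (-1.53 ± 0.27) and Edn2 (-2.43 ± 0.49) passed over all genes. That mean was -0.68 (camera adjusted p = 0.0302; adjusted p = 0.0867 with an estimated correlation), and the call ended without the 3 dimmest arrays (0.0714).

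The regulators induced by luteinizing hormone had 5 members that rose and 2 that fell of 15, with 7 and 2 over the list alone. Pde4d, a cyclic AMP phosphodiesterase, rose by 1.16 ± 0.25 and Tnfaip3 fell by 1.72 ± 0.22. The mean was 0.63, or -0.05 with the deposited signals (camera adjusted p = 0.0302; adjusted p = 0.265 with an estimated correlation). The interferon list had 1 member of 14 that rose, Usp18 (2.20 ± 0.46), over all genes and over the list alone, with a mean of 0.53, or -0.10 with the deposited signals (camera adjusted p = 0.0276; adjusted p = 0.214 with an estimated correlation). Of 16 circadian clock genes 7 rose and 4 fell, over all genes and over the list alone, without a call for the list (camera adjusted p = 0.0648): Cry2 (2.30 ± 0.29) and Dbp (2.05 ± 0.35) rose and Nfil3 (-1.29 ± 0.24) fell. Of 14 granulosa markers 3 rose over all genes and over the list alone, with a mean of 0.62, or -0.03 with the deposited signals (camera adjusted p = 0.0219; 0.0382 with an estimated correlation). Smooth muscle markers had no member that passed and a mean of -0.52 (camera adjusted p = 0.00493; 0.0382 with an estimated correlation). Of 15 endothelial markers 1 fell, and 8 over the list alone, with a mean of -0.55 (camera adjusted p = 0.00127; 0.0382 with an estimated correlation).

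None of the lists called in RU UF had more members called under median scaling or the deposited signals, and camera kept the call and direction of each. The circadian clock list, not called before, was called higher with median scaling (camera adjusted p = 0.0213). With median scaling 15 cholesterol synthesis and 4 steroidogenesis genes rose, and 7 hypoxia, 2 cell cycle, 4 protease, 4 progesterone receptor list and 7 structural matrix genes fell. The LH-induced list then had 3 members that rose and 2 that fell and the granulosa list 2 that rose. Where the signals were as deposited, with the median gene at -0.72, 1 steroidogenesis gene rose and no cholesterol synthesis gene, and 4 hypoxia, 3 progesterone receptor list and 1 protease genes fell. No endothelial marker passed under either. No cell cycle, structural matrix, interferon or LH-induced gene and 1 granulosa marker passed without normalization between arrays, and the LH-induced (5.30e-05), interferon (3.07e-04) and granulosa (8.42e-05) lists were called higher than the other genes by camera.

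Limma called 1579 probe sets in this comparison, 767 higher and 812 lower in RU UF, of which 751 differed at least 2-fold, and 1037 genes over 1 probe set per gene. The count fell to between 858 and 1032 when any of these 6 arrays was left out (897, 916 and 969 without control PoF 1, 2 and 3, and 1032, 858 and 953 without RU UF 1, 2 and 3), and to 793 with median scaling (286 higher and 507 lower) and 151 with the deposited signals (10 higher and 141 lower). It was 3108 without the 3 dimmest arrays, 3115 with only these groups in the fit and 3686 with array quality weights. With the deposited signals 23 of the 64 called probe sets that the naming rule gave kept their call, 40 lost it and 1 turned direction.

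**Figure D4:**
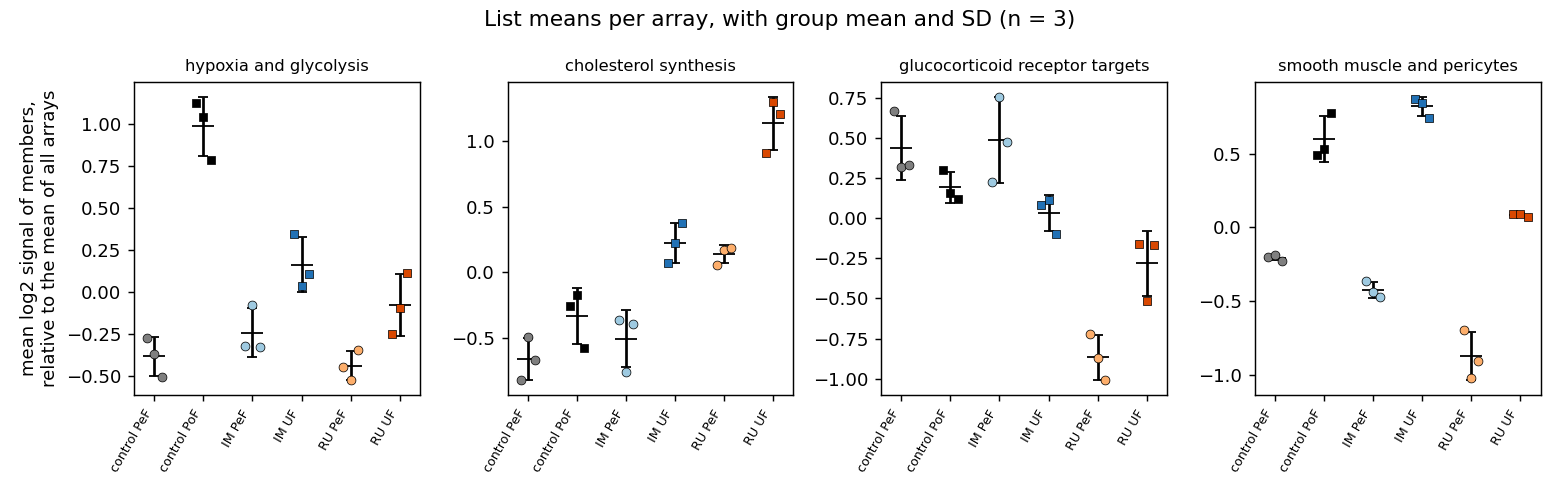
Mean log2 level of the hypoxia and glycolysis, cholesterol synthesis, glucocorticoid target and smooth muscle lists in each array (points), relative to the mean of the 18 arrays, with the group mean and SD (n = 3). The hypoxia list lay higher in control PoF than in IM UF and RU UF, and the glucocorticoid targets lay lower in RU PeF than in control PeF and IM PeF.

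Whether both drugs moved the same genes was asked at each time. At 22:00 limma called no probe set for IM, so none was shared, against a mean of 0.01 over 100 simulated draws of unchanged groups with the same controls. The log2 differences of the drugs from the shared control PeF samples had a correlation across genes, which are not independent replicates, of 0.494, where unchanged groups gave 0.440, and a covariance of 0.140, where unchanged groups gave 0.0608 ± 0.0442 (SD). At 10:00 all 6 probe sets lower in IM UF, those of Gbe1, Ndrg1, Hmox1, Ero1a, Xist and Egln3, were also lower in RU UF. The simulated draws shared 0, but they leave out the effects, and independent lists would share 0.268, which leaves out the shared controls, so the excess over either shows no shared effect. With array quality weights 731 were shared at 22:00 and 113 at 10:00, and without the 3 dimmest arrays 11 at 10:00, so the numbers shared hang on the setting. The weights of control PeF 1 to 3 were 0.474, 3.97 and 0.112. Both drugs were thus set mostly against control PeF 2 at 22:00, and the 731 may come from that shared array. The covariance at 10:00 was 0.0756, where unchanged groups gave 0.0747 ± 0.0385, and the correlation 0.361, where they gave 0.534. With 3 controls per time the controls could not be split, so part of any excess may come from the shared control samples. The log2 difference between replicates had an SD of 0.55, 1.15 and 1.06 in control PeF. In control PoF it was 0.44, 0.45 and 0.44. The simulated covariances, 0.0608 at 22:00 and 0.0747 at 10:00, did not carry this difference in control scatter. The covariances and correlations therefore cannot be judged against the simulated values, and a shared effect stays open at both times.

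The drugs were also compared with each other, although the doses and the hours of dosing differed. These differences set no control sample against the drugs, but the control arrays entered the normalization and the common estimate of the spread. In IM PeF against RU PeF the glucocorticoid targets were higher in IM PeF. Of 14 members 10 were higher, and 12 over the list alone, such as Fkbp5 (1.35 ± 0.21, SE, n = 3 per group, adjusted p = 5.35e-04), with a mean of 1.35 (camera adjusted p = 7.77e-13; 0.00119 with an estimated correlation). Cxcr4 was 51.4-fold higher in IM PeF (5.68 ± 0.35), Adamts1 5.47-fold (2.45 ± 0.27) and Tnfaip3 6.74-fold (2.75 ± 0.22). The progesterone receptor list had 5 members higher and 1 lower, with 6 and 2 over the list alone (mean 0.67, camera adjusted p = 0.0149; adjusted p = 0.0795 with an estimated correlation). Of 19 cholesterol synthesis genes 8 were lower in IM PeF, and 13 over the list alone (mean -0.65, camera adjusted p = 3.41e-09; adjusted p = 0.147 with an estimated correlation), with Dhcr7 at -1.30 ± 0.27. Of 32 structural matrix genes 8 were higher, and 11 over the list alone (mean 0.36, camera adjusted p = 8.70e-05; adjusted p = 0.179 with an estimated correlation). The immediate early genes had 1 member lower, Jund (-0.39 ± 0.09), over all genes and over the list alone (camera adjusted p = 0.0431; adjusted p = 0.636 with an estimated correlation). Smooth muscle markers had 2 members higher, and 4 over the list alone (camera adjusted p = 0.00827; 0.0416 with an estimated correlation), and granulosa markers 1 higher and 3 lower, with 1 and 4 over the list alone (camera adjusted p = 0.0444; adjusted p = 0.0709 with an estimated correlation). With median scaling 6 glucocorticoid targets, 2 structural matrix genes and 4 genes of the progesterone receptor list were higher, and 5 cholesterol synthesis genes and 2 of the progesterone receptor list lower. The deposited signals left 1 gene of the progesterone receptor list higher and 1 lower, and no gene of the other 3 lists passed, with each list still called by camera. Median scaling left no immediate early gene called, 1 smooth muscle marker higher, and 1 granulosa marker higher and 3 lower, and the deposited signals left none, with these 3 lists still called. Limma called 949 probe sets, 590 higher and 359 lower in IM PeF. The count was 493, 608, 486 and 596 without IM PeF 2, IM PeF 3, RU PeF 2 and RU PeF 3, 530 with median scaling (281 higher and 249 lower), 41 with the deposited signals (35 higher and 6 lower) and 3861 with array quality weights.

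In IM UF against RU UF the genes of steroid and cholesterol synthesis were lower in IM UF. Star was 3.24-fold lower (-1.698 ± 0.14, SE, n = 3 per group, adjusted p = 3.46e-06) and Cyp19a1 13.6-fold (-3.76 ± 0.49). Of 13 steroidogenesis genes 6 were lower, over all genes and over the list alone (mean -0.96, camera adjusted p = 9.40e-06; 0.0331 with an estimated correlation). Of 19 cholesterol synthesis genes 13 were lower, and 16 over the list alone, such as Lss (-2.05 ± 0.24) and Tm7sf2 (-1.73 ± 0.20) (mean -0.91, camera adjusted p = 3.82e-14; adjusted p = 0.0623 with an estimated correlation). Plat was 6.99-fold higher in IM UF (2.81 ± 0.45) and Lox 3.40-fold (1.77 ± 0.22). The protease list had 4 of 23 members higher, over all genes and over the list alone (camera adjusted p = 0.0391; adjusted p = 0.0971 with an estimated correlation), and the structural matrix list 8 of 32 higher and 1 lower, with 10 and 1 over the list alone (camera adjusted p = 2.16e-04; adjusted p = 0.124 with an estimated correlation). Of 13 smooth muscle markers 3 were higher, and 7 over the list alone (camera adjusted p = 6.75e-05; 0.00463 with an estimated correlation). Clock genes had 2 members higher and 6 lower, with 3 and 7 over the list alone, and angiogenic factors 1 higher, and 3 over the list alone; each list had a camera adjusted p of 0.0441 (adjusted p = 0.0971 with an estimated correlation). Leukocyte markers had 2 higher and 1 lower, with 3 and 1 over the list alone (camera adjusted p = 0.0306; adjusted p = 0.292 with an estimated correlation). With median scaling 4 steroidogenesis and 3 cholesterol synthesis genes were lower and 5 structural matrix genes higher with 1 lower, and with the deposited signals 1 steroidogenesis gene was lower and none of the other 2 lists passed, with each list still called by camera. Median scaling gave 3 proteases and 3 smooth muscle markers higher, 2 clock genes higher and 3 lower, 1 leukocyte marker each way and no angiogenic factor. The deposited signals left 1 protease higher and no member of those other lists, of which the angiogenic list alone lost its call (0.113). Limma called 1261 probe sets, 627 higher and 634 lower in IM UF. The count was 705 and 752 without IM UF 2 and 3, 805, 660 and 730 without RU UF 1 to 3, 557 with median scaling (316 higher and 241 lower), 32 with the deposited signals (18 higher and 14 lower) and 2643 with array quality weights. The clock and leukocyte calls ended without the 3 dimmest arrays (0.0710 and 0.120), and so did the immediate early gene and granulosa calls of IM PeF against RU PeF (0.385 and 0.0710).

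The treated follicles were followed from 22:00 to 10:00 as well, to ask which changes of the normal time course went on without rupture. In IM UF against IM PeF, Ptgs2 fell 142-fold (-7.14 ± 0.83, SE, n = 3 per group, adjusted p = 4.24e-06), Tnfaip6 19.95-fold (-4.32 ± 0.53) and Cyp19a1 20.9-fold (-4.39 ± 0.49), and Edn2 rose 11.97-fold (3.58 ± 0.49). In RU UF against RU PeF, Ptgs2 fell 391-fold (-8.61 ± 0.83, adjusted p = 4.32e-07), Tnfaip6 51.0-fold (-5.67 ± 0.53), Pgr 49.5-fold (-5.63 ± 0.74) and Cyp19a1 3.31-fold (-1.73 ± 0.49), while Edn2 differed by -0.21 ± 0.49 (0.771) and Star by 0.15 ± 0.14 (0.443). The fold of Pgr gives no exact size, since its RU UF level lay near the brightest unspiked control probe set of those arrays (signals of 6.73 to 7.27). Cell cycle genes fell in both: 11 of 28 with IM, and 13 over the list alone (camera adjusted p = 0.00192; adjusted p = 0.497 with an estimated correlation), and 14 with RU, and 16 over the list alone (camera adjusted p = 0.00134; adjusted p = 0.355 with an estimated correlation), such as Ccnb1 in RU (-0.91 ± 0.15). Cholesterol synthesis genes rose in both, 10 of 19 with IM (camera adjusted p = 0.00136; adjusted p = 0.494 with an estimated correlation) and 13 with RU (camera adjusted p = 8.81e-05; adjusted p = 0.355 with an estimated correlation), the same counts over the list alone. Smooth muscle markers rose in both, 10 of 13 with IM (camera adjusted p = 8.83e-05; 0.00514 with an estimated correlation) the same counts over the list alone, and 9 with RU, where 2 fell, with 10 and 2 over the list alone (camera adjusted p = 0.0109; 0.0485 with an estimated correlation).

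Other lists were called in 1 or both of these time courses. The regulators induced by luteinizing hormone fell, 9 of 15 with IM and 11 over the list alone (camera adjusted p = 0.00136; adjusted p = 0.350 with an estimated correlation), and with RU 9 fell and 1 rose, over all genes and over the list alone (camera adjusted p = 0.0452; adjusted p = 0.355 with an estimated correlation). Of 32 structural matrix genes 17 rose and 2 fell with IM, with 18 and 2 over the list alone (camera adjusted p = 0.00299; adjusted p = 0.494 with an estimated correlation), and 14 rose and 3 fell with RU, with 14 and 4 over the list alone (camera adjusted p = 0.0152; adjusted p = 0.355 with an estimated correlation); both calls ended with the deposited signals (0.0547 and 0.0972). With IM the progesterone receptor list had 7 members that fell and 1 that rose, with 8 and 1 over the list alone (camera adjusted p = 0.00920; adjusted p = 0.136 with an estimated correlation). With RU 7 of 14 interferon genes rose, with 9 that rose and 1 that fell over the list alone (camera adjusted p = 0.0204; adjusted p = 0.355 with an estimated correlation), and 9 of 20 immediate early genes fell and 1 rose, over all genes and over the list alone (camera adjusted p = 0.0395; adjusted p = 0.355 with an estimated correlation). The hypoxia and glycolysis list, called in the control time course, was not called with IM (10 rose and 3 fell of 23, 0.0675) or RU (9 rose and 3 fell, 0.120) by camera. The control call was itself lost (adjusted p = 0.140 with an estimated correlation), so the list was called in no time course there. With median scaling 4 cell cycle genes fell with IM and 13 with RU, 8 and 11 cholesterol synthesis genes rose, 10 smooth muscle markers rose in each, with 2 that fell with RU, and 14 and 11 structural matrix genes rose and 2 and 4 fell. The LH-induced list then had 7 members that fell with IM and 9 with RU, where 1 rose, the progesterone receptor list with IM 5 that fell and 1 that rose, the interferon list with RU 8 that rose, and the immediate early genes with RU 10 that fell and 2 that rose. The deposited signals left 2 LH-induced members that fell with IM and 4 with RU, 3 of the progesterone receptor list that fell and 1 that rose with IM, and with RU 1 interferon gene that rose and 2 immediate early genes that fell. They left 1 cholesterol synthesis gene that rose in each time course and no cell cycle, smooth muscle or structural matrix gene, and camera still called all of these lists except the structural matrix. Limma called 6052 probe sets in the IM time course, 2957 higher and 3095 lower, and 7052 in the RU time course, 3446 higher and 3606 lower. With the deposited signals these counts were 609 (272 higher and 337 lower) and 1038 (476 higher and 562 lower), and array quality weights gave 10149 in the IM time course.

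Whether a drug's effect differed between the times was tested as an interaction. For IM limma called 0 probe sets, and 1641 had an unadjusted p under 0.05. It called 5 with the deposited signals, all with a lower effect at 10:00, and 548 with array quality weights (244 higher and 304 lower). For RU it called 730, 396 with a higher and 334 with a lower effect at 10:00, a split that turned to 67 and 273 with median scaling and to 0 and 82 with the deposited signals. Among them were Edn2 (-4.38 ± 0.69, SE, n = 3 per group, adjusted p = 0.00152), whose RU effect was 1.96 at 22:00 and -2.43 at 10:00, and the metallothionein Mt1 (3.27 ± 0.41, adjusted p = 3.12e-04), whose RU effect was -2.58 at 22:00 and 0.69 at 10:00 (adjusted p = 0.168). The count of 730 went to 366 without control PoF 2, 340 with median scaling and 82 with the deposited signals, but to 1668 without the 3 dimmest arrays and 2446 with array quality weights.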

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

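The tests of the few indomethacin calls and of a uniform delay in RU UF were chosen only after the result was seen.

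The effect of RU486 differed between the times by the interaction test of limma for 730 probe sets. Of 100 drawn splits of the treatment labels within each time, 3 gave as many calls, the real one included. The highest other gave 2160, the split that turns the labels at 1 time and so tests the sum of the effects. Splits that mix treated and control samples weaken the drug's effect at that time and add it to the spread. They therefore cannot tell effects that differ between the times from equal ones, and the 3 decides nothing. For indomethacin the interaction test called 0 probe sets (1641 at an unadjusted p under 0.05, and 548 called with array quality weights). All 100 splits gave as many, which a real count of 0 fixes in advance, and the highest other gave 30. Of the 107 genes named as called in a comparison of RU486 with control, 46 had an effect that differed between the times. Over all 18155 probe sets the number was 730. The 107 genes were picked for large or clear changes at 1 time, which raises their share by itself. In 26 of the 46 the estimates had opposite signs. No call at both times was asked for, so these need not be reversals.

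Edn2 had a difference of -4.38 between its RU486 effects (adjusted p = 0.00152), Cyp19a1 of 2.81 (0.0301) and Star of 1.05 (0.00602), the last turning to -0.42 with the deposited signals. The 2.94 of Ptges rests on RU PeF signals at background, so it gives no exact size, and the gene's other probe set stood at -0.46, so a change of this gene stays open. Among lists, camera called the difference of the RU486 effects for steroidogenesis (0.78, adjusted p = 0.00193; adjusted p = 0.0925 with an estimated correlation) and cholesterol synthesis (0.67, adjusted p = 1.57e-06; adjusted p = 0.173 with an estimated correlation), whose means were -0.57 and -0.92 with the deposited signals, above a median gene at -1.54 and still called higher than the other genes (5.08e-05 and 0.00316). The glucocorticoid targets (0.84, adjusted p = 8.22e-05; adjusted p = 0.0894 with an estimated correlation) and the clock genes (0.46, adjusted p = 0.0146; adjusted p = 0.0925 with an estimated correlation) had means of -0.75 and -0.86 with the deposited signals and were still called higher than the other genes (8.29e-04 and 0.00241). The regulators induced by luteinizing hormone (0.505, adjusted p = 0.0146; adjusted p = 0.302 with an estimated correlation) and the interferon list (0.58, adjusted p = 0.0331; adjusted p = 0.302 with an estimated correlation) had means of -0.9996 and -0.56 there and were still called higher (0.0261 and 2.72e-05). Hypoxia and glycolysis (-1.01, adjusted p = 3.39e-05; adjusted p = 0.0967 with an estimated correlation) and the cell cycle (-0.59, adjusted p = 8.59e-04; adjusted p = 0.381 with an estimated correlation) had means of -2.44 and -2.09 there and were called lower than the other genes (3.75e-08 and 1.82e-04). The luteinizing hormone call ended without the 3 dimmest arrays (camera adjusted p = 0.262).

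For indomethacin, camera called the difference of the effects for cholesterol synthesis (0.41, adjusted p = 4.98e-05; adjusted p = 0.770 with an estimated correlation) and for smooth muscle markers (0.44, adjusted p = 2.16e-04; 0.00738 with an estimated correlation), whose means were -0.9993 and -0.84 with the deposited signals, above a median gene at -1.41 and still called higher than the other genes (0.0113 and 0.00106). Hypoxia and glycolysis (-0.96, adjusted p = 4.62e-10; 0.0452 with an estimated correlation) and the cell cycle (-0.47, adjusted p = 4.57e-04; adjusted p = 0.784 with an estimated correlation) had means of -2.26 and -1.85 there and were called lower than the other genes (4.36e-13 and 6.97e-05), and the cell cycle call ended without the 3 dimmest arrays (0.222).

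Indomethacin gave far fewer calls than RU486. At 10:00, 13 probe sets were called without the 3 dimmest arrays against 3108 for RU486, 171 against 3686 with array quality weights, and 7 against 3115 with only the compared groups in the fit, which argues against dim arrays and against a spread taken from other groups. At 22:00 the count was 0 with only the compared groups against 277 for RU486. That fit has fewer degrees of freedom and cut the RU486 count from 1348, so it cannot decide on the spread from other groups. Without the 3 dimmest arrays the indomethacin count at 22:00 was 0. With array quality weights it was 2348 against 3486, where control PeF 2 and IM PeF 3 took weights of 3.97 and 7.17, so dim or scattered arrays stay open there. A weaker effect of the drug or dose on these transcripts may remain, and it was not tested.

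Hypoxia and glycolysis genes were lower in both unruptured groups. With the Gapdh 3' minus 5' difference as a covariate the list's difference from control PoF was -0.79 ± 0.139 (SE) in IM UF, from -0.82 ± 0.122, and -1.03 ± 0.146 in RU UF, from -1.06 ± 0.122. The list's difference was thus kept after allowing for this measure. Gapdh is itself on the list as fixed, and its measure did not go with that of Actb, so RNA quality as a cause stays open. Without the 3 dimmest arrays the camera adjusted p in IM UF was 2.89e-14. It was 8.25e-22 with the deposited signals, 1.97e-16 with the replicate block and 0.00677 with the estimated correlation. Camera sets a list against the other genes, so the call with the deposited signals does not test for a difference in brightness. The call without the 3 dimmest arrays argues against IM UF 2, the only one of the dimmest arrays in these comparisons, as the cause in IM UF. The remaining IM UF arrays and all RU UF arrays still had lower median signals than every control PoF array, so a difference in brightness stays open. Both groups were compared with the same 3 control PoF arrays, so a shift of those arrays stays open. The lack of rupture is a biological explanation that may account for it and was not tested, since it goes with treatment.

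RU UF could have retained a pre-ovulatory profile. On the first principal component RU UF lay at 59.5 to 62.6, within the 54.9 to 67.1 of control PoF, while RU PeF lay at -66.8 to -64.6. These scores argue against a pre-ovulatory profile kept as a whole. Across probe sets, which are not independent replicates, IM UF minus RU UF had r = 0.0743 with the control time course. That r lay under the 0.2 that a delay was taken to need and above 0, so a partial delay stays open. The 113 probe sets that fell at least 8-fold in controls were higher in RU UF than in IM UF by a median of 0.0371 log2, with 52.2% of them higher. For the 131 that rose at least 8-fold the median of RU UF minus IM UF was -0.17, with 57.3% lower in RU UF. Both medians had the direction a delay predicts, but 52.2% and 57.3% are small majorities. The first median lay under the 0.2 log2 set as the bound against a uniform delay of all genes. Its members went both ways, with an SD of 1.08. Ptgs2, Pgr and Tnfaip6 differed by 0.09 ± 0.83 (SE), 0.49 ± 0.74 and 0.06 ± 0.53, each with an error larger than itself. Pgr was above background on 1 of 3 IM UF arrays. A small uniform delay therefore stays open. With the Gapdh covariate 246% of the slope was kept (0.0407 before, 0.1002 after), above the bound set against RNA quality, but with hardly any slope to explain the test could not decide.

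Splits of 3 against 3 samples are too few for a share under 0.05. The other splits also mix the real groups, so a real difference adds to their spread. Low counts in them follow from that and do not measure how often chance gives such counts. The real count and the highest of the other 9 splits were 7183 and 0 for control PoF against control PeF, 1348 and 3 for RU PeF, 6 and 0 for IM UF and 1579 and 0 for RU UF, each against its control. They were 6052 and 0 and 7052 and 0 for the IM and RU time courses, 949 and 2 for IM PeF against RU PeF and 1261 and 0 for IM UF against RU UF; in each of these 8 comparisons 1 of 10 splits gave as many. For IM PeF the real count was 0, all 10 splits gave as many, and the highest other was 477, in the split that set control PeF 1, IM PeF 2 and IM PeF 3 against the rest, which points to a structure of the samples.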

How the results depend on the processing

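Array quality weights and the fit without the 3 dimmest arrays were chosen only after the data were seen, and the signals as deposited were the setting first planned. A setting that left out arrays by their place along the first component was tried and removed, since that place follows the outcome. The cause was not tested for any change given here, except where fewer arrays were used. Of 334 calls of named probe sets, counted once per comparison, 132 kept call and direction with the deposited signals, 185 lost the call and 17 turned. The numbers that kept it were 286 with median scaling, 325 with no pseudocount, 327 with a pseudocount at the median, 314 with no filter, 330 with a robust variance model, 309 with no variance trend, 333 with weights, 321 without the 3 dimmest arrays, 286 with only the compared groups and all 297 tested at the 75th percentile; 258 kept it whichever array was left out. Changes of sign in genes called in neither fit were counted as unmoved.

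With the deposited signals the median of all tested probe sets shifted by 1.28 in control PoF against control PeF, 0.60 in IM PeF, 0.77 in RU PeF, -0.75 in IM UF, -0.67 in RU UF, -0.14 in the RU time course, -0.19 in IM PeF against RU PeF, and -1.36 and -1.45 in the IM and RU interactions. With median scaling the shifts over 0.1 were 0.26 in controls, 0.20 in IM PeF, 0.28 in RU PeF, -0.10 in RU UF, and -0.26 and -0.39 in the interactions. Calls with the deposited signals were 22 in RU PeF, 151 in RU UF, 609 in the IM and 1038 in the RU time course, 41 and 32 in the drug comparisons at 22:00 and 10:00, and 5 and 82 in the interactions. Of the 17 pathway lists, without the cell type lists, those called were 7 in controls, 5 in IM UF, 10 in the RU time course, 8 in IM PeF against RU PeF and 7 in the IM interaction. With median scaling 893 were called in RU PeF, 793 in RU UF, 530 and 557 in the drug comparisons and 340 in the RU interaction, with 4 pathway lists in controls, 0 in IM PeF, 10 in IM UF against RU UF and 7 in the IM interaction.

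Signs that turned with the deposited signals in control PoF against control PeF were Ctsb 0.64, Icam1 0.43, Bub1b 0.56, Ccne2 0.64, Ube2c 0.93, Jund 1.12, Des 0.32, Kdr 0.64, Emcn 0.75 and Star 0.42. In RU PeF they were Pgk1 0.0524, Per1 0.13, Prlr 0.0376, Tek 0.0224 and Emcn 0.26, in RU UF Jund -0.24, and in the RU interaction Star -0.42. Without the 3 dimmest arrays Akr1c3 in the IM time course was -0.55.

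Array quality weights gave 2348 calls in IM PeF, 3486 in RU PeF, 171 in IM UF, 3686 in RU UF, 10149 in the IM time course, 3861 and 2643 in the drug comparisons, and 548 and 2446 in the interactions, with 731 and 113 shared between the drugs. Control PeF 2 and IM PeF 3 carried most of the weight of their groups in these fits. Without the 3 dimmest arrays there were 2248 in RU PeF, 13 in IM UF, 3108 in RU UF and 1668 in the RU interaction, 4 pathway lists in IM PeF and 7 in RU PeF, and 11 shared at 10:00. Only the compared groups gave 277 in RU PeF and 3115 in RU UF. The mean of all probe sets of a gene left every count of pathway lists within 1.5 times. No variance trend gave 1 in IM PeF and a pseudocount at the median 14 in IM UF. The 75th percentile filter gave 3 pathway lists in the RU time course and 5 in the RU interaction. With the estimated correlation the pathway lists called were 0 in controls, 0 in IM PeF, 1 in IM UF, 3 in RU UF, 0 in each treated time course, 1 in each drug comparison, and 1 and 0 in the interactions.

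Leaving out 1 array gave 5608 to 7883 calls in controls, 0 to 27 in IM PeF (27 without control PeF 2), 623 to 1639 in RU PeF (623 without RU PeF 3, 710 without RU PeF 2), 1 to 17 in IM UF (17 without IM UF 1, 2 without control PoF 2, 1 without control PoF 1, IM UF 2 or IM UF 3) and 858 to 1032 in RU UF, where any array moved it over 1.5 times. It gave 4560 to 6444 and 5841 to 6031 in the time courses, 486 to 1169 in IM PeF against RU PeF (493 and 608 without IM PeF 2 and 3, 486 and 596 without RU PeF 2 and 3), and 660 to 920 in IM UF against RU UF (705 and 752 without IM UF 2 and 3, 805, 660 and 730 without RU UF 1 to 3). The interactions had 0 to 0 and 366 to 925 (366 and 433 without control PoF 2 and 3, 431 and 427 without RU PeF 2 and 3, 443, 446 and 465 without RU UF 1 to 3).

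A replicate block, which treats equal sample numbers as pairs, gave 1123 calls in RU PeF and 1382 in RU UF, kept 328 of the 334 named calls, and ended the angiogenic and clock calls of IM UF against RU UF (camera adjusted p = 0.0535 each). The labels give no such pairing: of 45 pairs of equally numbered samples 1 had a correlation over 0.1, no comparison of 15 had all 3 over it, and in 14 of the 45 the equally numbered sample had the highest correlation of the 3, where no pairing would give 15.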

Other observations

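No test was added here after its result was seen. Genes of prostaglandin handling moved in both directions in the control time course, where 3 of 14 rose and 3 fell, over all genes and over the list alone (camera adjusted p = 0.634). The prostaglandin exporter Abcc4 rose by 3.35 ± 0.34 (SE, n = 3 per group) and the phospholipase Pla2g4a, which releases arachidonic acid, fell by 3.17 ± 0.46. Of 6 cumulus matrix genes 1 rose and 2 fell, over all genes and over the list alone (0.388), with versican (Vcan) at -2.71 ± 0.16. Of 15 cytokines and chemokines 1 rose and 3 fell, over all genes and over the list alone (0.354), of 14 angiogenic factors 6 rose and 3 fell, with 7 and 3 over the list alone (0.542), and of 15 luteal genes 4 rose and 4 fell, over all genes and over the list alone (0.867), all with camera. The luteal list had a median of -0.25 and a mean of -0.04.

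In RU UF against control PoF the angiogenic list had 2 members that rose and 4 that fell of 14, with 2 and 6 over the list alone (camera adjusted p = 0.0648), and the vessel-destabilizing ligand Angpt2 fell by 1.49 ± 0.26. Of 20 immediate early genes 2 rose and 5 fell, over all genes and over the list alone (0.456), with the phosphatase Dusp1 at -2.17 ± 0.28. Of 15 luteal genes 3 rose and 2 fell, with 4 and 2 over the list alone (0.456), and the protease inhibitor A2m fell by 2.23 ± 0.42. Of 14 prostaglandin genes 1 rose and 2 fell, with 3 and 4 over the list alone (0.304), and the prostaglandin-degrading enzyme Hpgd fell by 1.58 ± 0.31.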
